A study of Mus musculus with 10 samples.

How the data were processed

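RNA-seq libraries of mouse embryonic stem cells were used from 2 experiments of 1 series. In the first, cells carry loxP-flanked Kdm4a, Kdm4b and Kdm4c and a tamoxifen-activated Cre recombinase (CreERT2) at the Rosa26 locus. The labels give 2 untreated control libraries (Ctrl) and 2 triple knockout libraries (TKO), the latter grown in 500 nM 4-hydroxytamoxifen for up to 72 h. In the second, a reporter line carrying Zscan4-GFP and MERVL-tdTomato overexpressed 6 constructs, with 1 library each: full-length JMJD2C (JMJD2C_FL), JMJD2C with a truncated intrinsically disordered region (JMJD2C_Mut), that mutant joined to a disordered region taken from human HNRNPA (JMJD2C_Mut_hIDR1) or human FUS (JMJD2C_Mut_hIDR2), and each disordered region alone (hIDR1, hIDR2). JMJD2C is the protein of Kdm4c. Total RNA was used, and the labels describe serum medium with leukaemia inhibitory factor and inhibitors of GSK3 and MEK for all cells.

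Gene counts for both experiments were deposited as integer counts per Ensembl gene, and repeat counts per repeat copy for the overexpression libraries. For the libraries of both experiments the authors also supplied RPKM per gene. Per the submitters' processing notes, Trim Galore 0.6.7, STAR, HTSeq, bedtools and edgeR were used with the mm9 genome; the role and order of each, and the strand of the libraries, are not given in the sources used here. RPKM was checked against the counts: 24566 of 24566 genes with values fitted 1 length per gene across libraries, at a relative tolerance of 1e-09. All 26 sample columns were used and 0 were left out. The gene tables hold 37620 Ensembl identifiers. Symbols were matched by identifier for 32897 of them, and the 4723 without a symbol held 0.513% of the counts. The annotation available here is GENCODE M21 on GRCm38, another build than the files use, so it supplied only each gene's chromosome, by identifier, and no coordinates are given.

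Total gene counts were 51.9 to 68.2 M in the 4 knockout libraries and 27.1 to 31.5 M in the 6 overexpression libraries. Repeat counts totalled 268 to 333 M per overexpression library, 9.45 to 11.0 times the gene counts. A read may thus be counted at more than 1 repeat copy, but this was not tested. Read totals are not given in the sources used here. At these depths the 95% exact Poisson interval of a gene at 135 CPM spans 131 to 139 CPM.

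For TKO against Ctrl, counts were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit, glmQLFTest), and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The common biological coefficient of variation was 3.47%. Gene lists fixed before the data were examined were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 16 lists. Same-numbered Ctrl and TKO libraries did not deviate together (r = -0.00617 across genes, which are not independent replicates), and the main model has no replicate block.

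With 1 library per construct the overexpression data allow no test. TMM-scaled CPM were compared as log2 ratios, with a prior count of 2, over 5 pairs: JMJD2C_FL, JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2 each against JMJD2C_Mut, JMJD2C_Mut_hIDR1 against hIDR1, and JMJD2C_Mut_hIDR2 against hIDR2. Genes with a mean of at least 1 CPM over the pair were kept, and ratios of at least 2-fold were counted. Each list's median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Ratios of counts carry exact conditional binomial 95% intervals. For a gene with 0 counts in 1 library of a pair, the lower 95% limit of the ratio is given. Intervals and these limits cover counting error only. For the correlation of pairs that share JMJD2C_Mut, 20 simulations with no difference between libraries gave the values that the shared library alone produces. Their noise was negative binomial, with the spread between the knockout libraries of a group. Those replicates may be technical, so differences between cultures may not be covered. Repeat counts were summed per repeat name, scaled to CPM of the repeat total and compared as log2 ratios, with intervals from a bootstrap over copies; 31 repeat names were fixed in advance.

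The lists, with the number of genes found in the tables, were 2C-like (34 of 51 symbols), naive pluripotency (24), primed pluripotency (13), primitive endoderm (18), trophectoderm (13), mesoderm and neural (14 of 15), fibroblast (13), germline (22), H3K9 and DNA methylation machinery (19), p53 targets (18), cell cycle (22), interferon response (18), imprinted (15 of 18), hypoxia and glycolysis (16), mitochondrial transcripts (11) and histones (9 of 10). For the overexpression pairs, the genes called up and down in TKO were added as lists. Genes are named by a fixed rule. For TKO these are Kdm4a to Kdm4d, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 1 CPM and no overlap between groups, and the 4 members of each list with the largest changes. For the overexpression pairs they are Kdm4c, Hnrnpa1, Fus, the 10 highest and 10 lowest ratios for JMJD2C_FL against JMJD2C_Mut, 5 and 5 for the other pairs (at least 1 CPM in 1 library and 50 counts over both), and 4 members of each list. Symbols of the Gm and Rik kinds are named only as list members. Any gene named outside this rule is said to have been chosen after its values were seen.

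The code was tested on simulated data. For 200 genes planted in 16511, recovery was 56.7% at 1.5-fold, 80.6% at 2-fold and 89.4% at 4-fold, with 5 false calls. A planted list had an adjusted p of 2.11e-23 with camera and 0 of 19 unchanged lists were called. A planted list reached percentile 100 and 0 of 20 unchanged lists fell outside the central 95%.

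Alternatives covered DESeq2 1.42.0, RLE scaling, library sizes only, no filter or a filter on mean CPM, RPKM with limma, a replicate block, leaving out each library, an estimated inter-gene correlation, and, for the pairs, other prior counts, filters, thresholds and repeat denominators. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.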

Results

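RNA-seq of mouse embryonic stem cells was compared in 2 experiments. The first deletes the loxP-flanked histone demethylase genes Kdm4a, Kdm4b and Kdm4c with a tamoxifen-activated Cre recombinase, with 2 untreated control libraries (Ctrl) and 2 triple knockout libraries (TKO). It asks which genes change when these enzymes, which remove methyl groups from H3K9 and H3K36, are lost. The second overexpresses JMJD2C, the Kdm4c protein, or variants of its disordered region in a line with reporters for Zscan4 and the endogenous retrovirus MERVL, which mark cells resembling the 2-cell embryo (2C-like cells). It asks whether the disordered region matters for gene expression, with 1 library for each of 6 constructs and so no replicates. Total gene counts were 51.9 to 68.2 M per library in the knockout experiment and 27.1 to 31.5 M in the overexpression experiment. The labels do not say whether libraries of a group come from separate cultures, so replicates may be technical, and p-values measure only the spread between these samples.

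Reads on the target genes fell in TKO but remained (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; n = 2 and 2 throughout; ± is SD). Kdm4b (ENSMUSG00000024201) fell by 1.90 on the log2 scale (SE 0.05, adjusted p = 6.2e-22), from 77.5 ± 1.72 to 20.8 ± 0.486 CPM (TMM-scaled counts-per-million). Kdm4c (ENSMUSG00000028397) fell by 1.47 (SE 0.05, adjusted p = 1.23e-20), from 101 ± 2.64 to 36.5 ± 0.978 CPM. Kdm4a (ENSMUSG00000033326) fell by 0.48 (SE 0.04, adjusted p = 4.17e-11), with 126 and 119 CPM in Ctrl and 87.9 and 88.3 CPM in TKO. Kdm4d, which was not targeted, had 1 to 3 counts per library and was not tested. Counts cover whole genes, so transcripts that lack only the deleted exons are still counted.

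**Figure D1:**
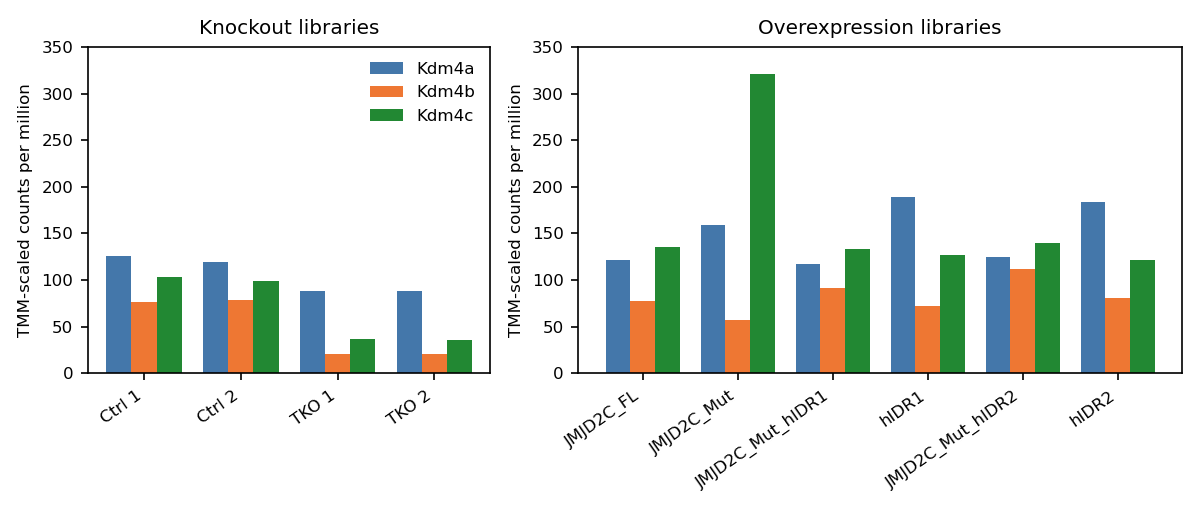
Bars show TMM-scaled CPM of Kdm4a, Kdm4b and Kdm4c in each library, for the 4 knockout libraries (left) and the 6 overexpression libraries (right), without error bars because each bar is 1 library. Kdm4c is at 321 CPM in the library labelled JMJD2C_Mut and between 121 and 140 CPM in the other overexpression libraries.

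Most genes that passed the main filter differed between TKO and Ctrl. Of 16511 genes tested, 10012 (60.6%) were called by edgeR at an adjusted p below 0.05, 4825 up and 5187 down. Many changes were small: the median absolute log2 fold change of called genes was 0.48. At least 2-fold changes numbered 2415, of which 1574 were up and 841 down, and 1257 when only genes with a mean of at least 1 CPM were kept. The balance of directions depended on scaling. Up genes made 48.2% of calls with TMM, 58.6% with library sizes only and 59.6% with RPKM. The share of genes called was lower with DESeq2 (8484 of 18884), no filter (10069 of 24398) and log2(RPKM + 0.1) (7762 of 24398). It was higher at a mean CPM of at least 1 (8881 of 12977). TKO lay wholly above Ctrl for 6444 genes and wholly below for 6612, where chance gives 16.7% of genes each way. The treated libraries also received tamoxifen and active Cre, and no library with either alone was analysed here, so these effects cannot be separated from the knockout. Mitochondrial transcripts took 1.81% and 1.80% of counts in Ctrl and 2.39% and 2.18% in TKO.

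Among the genes highest in TKO, Nt5e, the cell surface enzyme that makes adenosine, rose by 5.55 on the log2 scale (SE 0.13, edgeR adjusted p = 4.98e-23), from 0.507 to 23.7 CPM. The D-type cyclin Ccnd2 rose by 5.01 and the chemokine gene Cxcl10 by 4.92 (SE 0.17 and 0.43). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose by 4.25 (SE 0.07, adjusted p = 3.69e-26), from 3.45 to 65.9 CPM. The growth factor gene Bmp4 rose by 4.19 (SE 0.17). Pdzrn4, Samd4, Ptgs2, Foxd1, Itgb2, Thbs1 and Robo4 rose by between 4.00 and 4.36. Among the genes that fell most, the calcium pump gene Atp2b2 had a log2 fold change of -4.39 (SE 0.14, edgeR adjusted p = 3.44e-20), from 15.8 ± 0.165 to 0.749 ± 0.0576 CPM. Il3ra, Fgg, Myom2, Dner, Fhad1, Atp6v0a4, Fxyd2, Grin1, Ly6g6e and Pygl had log2 fold changes between -4.15 and -3.21. Otx2, a homeobox gene of primed pluripotency and the early nervous system, fell by 3.29 (SE 0.10, adjusted p = 1.34e-20), from 26.2 ± 1.89 to 2.68 ± 0.320 CPM.

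The 2C-like list rose from a very low level. Of its 34 genes in the tables, only 18 passed the filter and were tested. Of these, 15 were called up and 2 down by edgeR, with the same counts adjusted over the list alone. Their median log2 fold change was 2.63 (mean 2.40). A gene near 0 in Ctrl can pass the filter only through its TKO counts. For such genes the upward direction was fixed by the filter, which adds to these counts. Other lists with untested members share this limit. Zscan4f rose by 4.43 (SE 0.67, adjusted p = 2.14e-06), from 0.0318 to 0.754 CPM. Gm2016 and Usp17le rose by 3.48 and 3.44. Usp17la, with 1 count in the Ctrl libraries, rose by 5.67 (SE 1.03). Most of these genes belong to multigene families whose members can share reads, so single members are uncertain. The list ranked above other genes with camera at the preset correlation (adjusted p = 0.0369) but not with an estimated correlation (adjusted p = 0.380) or with library sizes only.

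Naive pluripotency genes moved both ways. Of 24 genes, 10 were called up and 12 down, also when adjusted over the list alone, with a median of -0.14. Dppa3, a maternal factor that protects DNA methylation at imprints, had a log2 fold change of -2.50 (SE 0.08), from 32.8 to 5.81 CPM. Sox2 fell by 0.82, from 647 to 366 CPM, Dppa5a fell by 0.81 and Nr0b1 rose by 0.86. The camera call was downward (adjusted p = 0.0406; adjusted p = 0.380 with an estimated correlation) and was also lost with library sizes only, with a replicate block and without either TKO library. Primed pluripotency genes (12 tested, 4 up and 6 down, the same adjusted over the list alone) were not called as a list by camera (adjusted p = 0.286), with Otx2 down and Cdh2, Sox3 and Dnmt3a up by 1.90, 1.85 and 1.19.

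Lineage lists were not called as lists by camera either, although single members rose. Primitive endoderm genes had 9 of 16 up and 3 down (median 0.64, adjusted p = 0.561), with Cubn up by 3.40, Gata6 by 1.67, Pdgfra by 1.47 and Hnf4a by 1.28. Trophectoderm genes had 5 of 11 up and 5 down (median 0.37, adjusted p = 0.780), with Cdx2 up by 2.27, Hand1 up by 1.90, Krt8 up by 2.23 from 14.4 to 67.5 CPM, and Krt7 at -1.87. Mesoderm and neural genes had 2 of 9 up and 3 down (adjusted p = 0.982). Their median (0.49) and mean (0.19) were positive while the direction of the test was down; T rose by 2.12, Gsc had a log2 fold change of -2.68, and Kdr and Pax6 were not called. Fibroblast genes, which would mark feeder cells, had 7 of 8 up and 1 down (median 1.19, adjusted p = 0.0897), among them Tagln (2.75), Col1a2 (2.40), Pdgfrb (1.33) and Twist1 (1.21). All these counts were the same adjusted over the list alone.

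Hypoxia and glycolysis genes fell without exception. All 16 were called down, also adjusted over the list alone, with a median of -1.21 (camera adjusted p = 6.03e-52; adjusted p = 0.0936 with an estimated correlation). Bnip3, a mitophagy receptor, fell by 2.29 (SE 0.04, edgeR adjusted p = 3.21e-25), from 142 to 29.1 CPM. Vegfa fell by 2.06, from 187 to 45.0 CPM, Ndrg1 fell by 2.11 and the phosphofructokinase gene Pfkp fell by 1.98.

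Targets of p53 rose as a list (10 of 18 up, 2 down, the same adjusted over the list alone; camera adjusted p = 4.89e-08; adjusted p = 0.174 with an estimated correlation). The median was 0.19 and the mean 0.56, since a few genes carried large changes. Mdm2, which encodes the ligase that degrades p53, rose by 1.39 from 201 to 527 CPM, Plk2 rose by 2.10 from 40.5 to 173 CPM, Fas rose by 2.74 and Perp by 1.29. Imprinted genes rose too, with 11 of 15 up and 2 down, the same adjusted over the list alone (median 0.69, camera adjusted p = 2.32e-06; adjusted p = 0.174 with an estimated correlation). Igf2, a fetal growth factor gene, rose by 2.30 from 5.70 to 28.0 CPM, and Dlk1, Mest and Cdkn1c rose by 2.09, 1.40 and 1.26.

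Germline genes fell on balance, with 3 of 20 up and 11 down, the same adjusted over the list alone (median -0.39, camera adjusted p = 0.0344; adjusted p = 0.380 with an estimated correlation), and the call was also lost without TKO replicate 2. The meiotic cohesin genes Smc1b and Stag3 fell by 2.05 and 1.60, Stag3 from 73.6 to 24.2 CPM, while Tex101 and Taf7l rose by 2.45 and 1.29. Mitochondrial transcripts rose in 8 of 11 cases and fell in none, also adjusted over the list alone (median 0.23, camera adjusted p = 0.0344; adjusted p = 0.582 with an estimated correlation; also lost without Ctrl replicate 2), with mt-Nd1 up by 0.52, mt-Cytb by 0.38, mt-Rnr1 by 0.29 and mt-Nd4 by 0.27.

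The remaining lists were not called by camera. Genes of the H3K9 and DNA methylation machinery had 4 of 19 up and 8 down (median -0.04, adjusted p = 0.335), with small changes in Atf7ip (-0.61), Chaf1b (-0.45), Cbx3 (-0.39) and Hdac1 (-0.36). Cell cycle genes had 4 of 22 up and 15 down (median -0.17, adjusted p = 0.0757), with Ccnb2 at -0.68, Bub1 at -0.47, Mcm6 at -0.38 and Ccnd1 at 0.63. Interferon response genes had 4 of 9 up and 2 down (median 0.45, adjusted p = 0.335), with Cxcl10, Ddx58 (1.68) and Irf7 (1.28) up and Ifitm3 (-0.87) down. Those counts were the same adjusted over the list alone. Histone genes had 1 of 7 down, Hist1h1b at -1.09, and 0 adjusted over the list alone (median 0.32, camera adjusted p = 0.761). In all, camera called 7 of 16 lists at the preset correlation and 0 with an estimated one, where 3 had an unadjusted p below 0.05. The estimated correlation was below the preset 0.01 for the 2C-like (-0.0027), germline (0.0077), p53 (-0.027) and imprinted (-0.038) lists. Stronger correlation among their members thus does not account for those lost calls. The estimate was higher for the naive pluripotency (0.035), hypoxia (0.041) and mitochondrial (0.69) lists. The fry test, which asks whether a list moves one way and does not compare it with other genes, called 12.

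**Figure D2:**
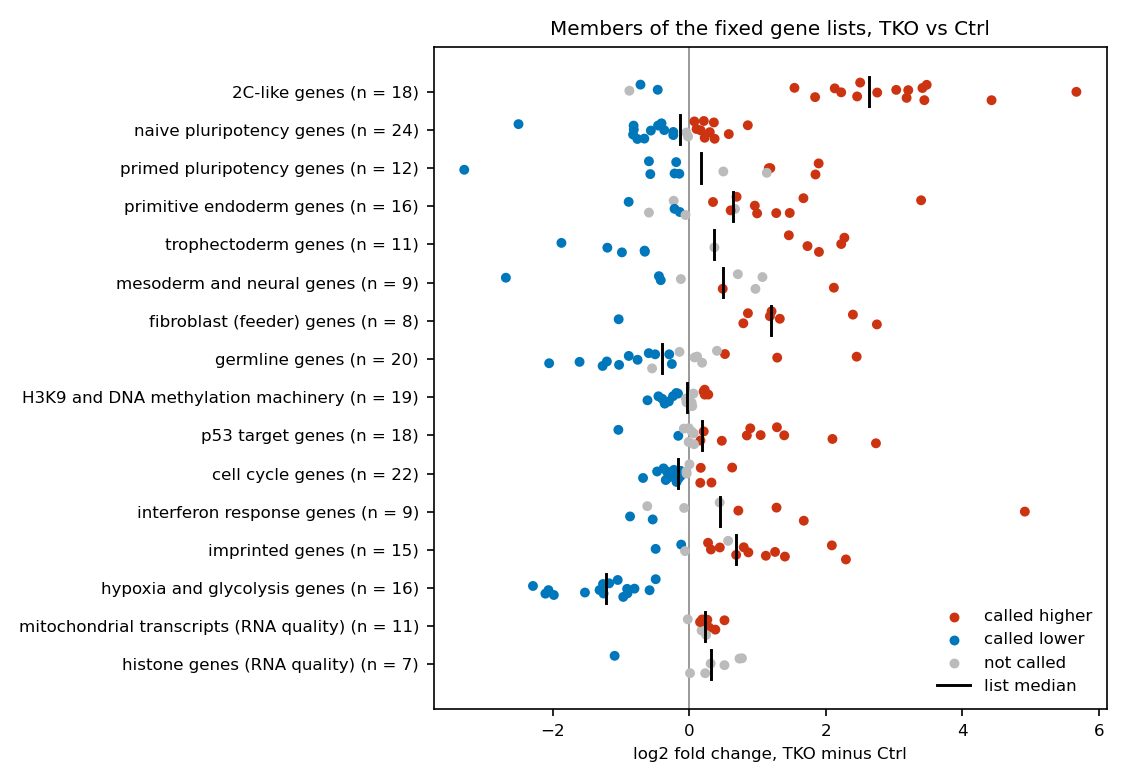
Each point is 1 gene of a fixed list, placed by its log2 fold change in TKO relative to Ctrl (2 libraries each), coloured by the edgeR call, with a black bar at the list median. All 16 hypoxia and glycolysis genes lie below 0, and 15 of the 18 2C-like genes that passed the filter are called above it.

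In the overexpression libraries Kdm4c reads did not follow the labels. The library labelled JMJD2C_FL had 135 CPM (95% exact Poisson interval 131 to 139), JMJD2C_Mut had 321 (315 to 328), JMJD2C_Mut_hIDR1 had 134 (130 to 138) and JMJD2C_Mut_hIDR2 had 140 (136 to 144). The libraries labelled hIDR1 and hIDR2, which should carry no JMJD2C construct, had 127 (123 to 131) and 121 (117 to 126). JMJD2C_Mut was thus at 2.39 times the median of the 6 and the others at 0.903 to 1.04 times. Kdm4a was at 117 to 189.6 CPM and Kdm4b at 56.7 to 112 CPM. Hnrnpa1 was at 538 to 658 CPM and Fus at 229 to 318 CPM. Construct sequences are not given in the sources used here, so a construct that differs from the mouse gene, as the human disordered regions do, may not be counted on it. Libraries are therefore named by their labels, and every direction between them rests on labels that Kdm4c does not bear out. A ratio of 2 libraries compares those libraries and not the conditions.

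Between 1086 and 2301 genes differed by at least 2-fold in each pair. JMJD2C_FL had 849 genes higher and 457 lower than JMJD2C_Mut, of 13962. Against the same library, JMJD2C_Mut_hIDR1 had 867 higher and 556 lower, and JMJD2C_Mut_hIDR2 had 866 higher and 220 lower. JMJD2C_Mut_hIDR1 had 1203 higher and 1098 lower than hIDR1, a balance that turned to 532 higher and 757 lower at a mean CPM of at least 5 and to 1022 and 1084 without X and Y genes. JMJD2C_Mut_hIDR2 had 1487 higher and 742 lower than hIDR2. The median over all genes was between -0.07 and -0.04 in every pair. X-linked genes contributed to the higher side, with medians of 0.79, 0.65, 0.61, 0.51 and 0.45 over 544 genes in the same order of pairs. In JMJD2C_FL against JMJD2C_Mut, 194 X-linked genes (35.7%) were at least 2-fold higher, compared with 4.56% of autosomal genes. The highest autosomal median there was 0.20.

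**Figure D3:**
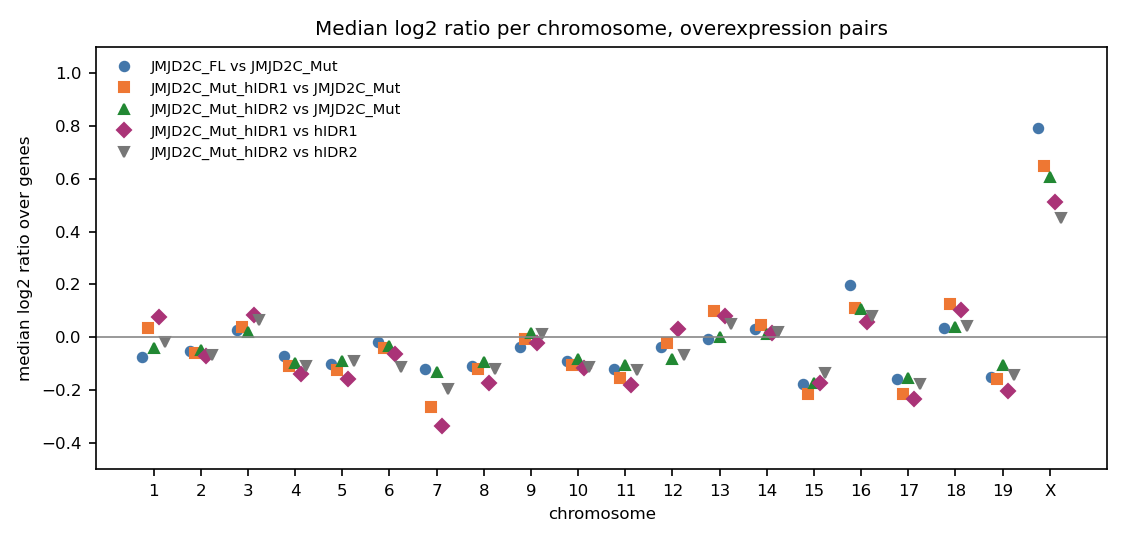
Points show the median log2 ratio of the genes on each chromosome for the 5 pairs of overexpression libraries. The X chromosome lies between 0.45 and 0.79 in every pair, above every autosome.

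The 10 genes highest in the library labelled JMJD2C_FL relative to JMJD2C_Mut included members of the Magea and Xlr families and 1 gene of the 2C-like list, Pramel7. Magea8 had 267 counts against 0, at least 70.6-fold higher, and Pet2, Magea2 and Magea6 were at least 28.8-, 21.1- and 18.2-fold higher. Magea5 had 180 counts against 1, a ratio of 177 (31.3 to 7021), Xlr4c a ratio of 105 (18.5 to 4189) and Spink1 a ratio of 92.3 (16.2 to 3685). Pramel7 had a log2 ratio of 5.33, Xlr4a 5.52 and Xlr3c 4.84. Magea, Xlr and Pramel genes belong to multigene families whose members can share reads. On the lower side, Ankrd34a had 3 counts against 52, a ratio of 0.0567 (0.0113 to 0.175), and the metal transporter gene Slc11a1 a log2 ratio of -2.81, with 6.82 against 48.2 CPM (ratio 0.141, 0.122 to 0.163). Il12rb1, Napsa, Muc4, Abcg4, Atp4a, Calb2, Zglp1 and Cpne9 had log2 ratios between -2.56 and -2.17.

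The other pairs shared many of these genes. Against JMJD2C_Mut, Magea8 and Pet2 were at least 63.3- and 33.2-fold higher in JMJD2C_Mut_hIDR1, where Pramel3 had a log2 ratio of 5.26. They were at least 62.2- and 36.8-fold higher in JMJD2C_Mut_hIDR2, where Xlr4a had 5.20. Slc11a1 was lower in both (-3.41 and -3.16), with Spi1 (2 counts against 54, a ratio of 0.0357, 0.00422 to 0.135), Chac1 (-2.69), Nupr1 (-2.65) and Atcay (-2.54) lower in JMJD2C_Mut_hIDR1, and Slc25a29 (-2.50), Il23a (-2.43), Hsd17b1 (-2.32) and Ucp1 (-2.30) lower in JMJD2C_Mut_hIDR2. Relative to hIDR1, JMJD2C_Mut_hIDR1 was at least 18.99-fold higher for Kcnj2, 17.94-fold for Tsga8 and 17.15-fold for Cyp4a12b. It was lower for Chac1 (-3.74), Ubap1l (-3.36), Nkx6-3 (-3.26), Nupr1 (-3.12) and Hnrnpa1l2-ps (-5.88). That processed pseudogene of the hnRNP A1 family had 574 counts in hIDR1 and 2 to 8 in the other libraries, with 8 in JMJD2C_Mut_hIDR1, which is labelled as carrying the same human region. Whether these are reads of the human construct, and not of the mouse pseudogene, cannot be told from the tables. Relative to hIDR2, Xlr5a had a ratio of 222 (39.5 to 8803) in JMJD2C_Mut_hIDR2. This library was at least 81.9-fold higher for the imprinted RNA H19 and 36.2-fold for Xlr4b. It was lower for Chac1 (-3.22), Lefty1 (-3.19), Nkx6-3 (-3.09) and Lefty2 (-3.08); Chac1 encodes a stress-induced enzyme that degrades glutathione.

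The 2C-like list was higher in the libraries labelled JMJD2C_FL, JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2 in all 5 pairs. Against JMJD2C_Mut, the medians were 1.73, 2.11 and 1.84, with 27 of 31, 27 of 31 and 30 of 32 genes at least 2-fold higher and none 2-fold lower. JMJD2C_Mut_hIDR1 against hIDR1 had a median of 3.81 (29 of 30 genes), and JMJD2C_Mut_hIDR2 against hIDR2 had 4.31 (28 of 30). Each median was at percentile 100 of matched random lists. Pramel7 had log2 ratios of 4.04 and 4.02 and Pramel6 of 3.48 and 3.06 for the mutants with hIDR1 and hIDR2 against JMJD2C_Mut. Usp17la had 70.5 CPM in JMJD2C_Mut_hIDR1 and 7.76 in JMJD2C_Mut. Relative to hIDR1, Usp17la, Gm12794 and Usp17lb had log2 ratios of 4.95, 4.89 and 4.83. Relative to hIDR2, Usp17le had 5.47, and Ubtfl1, with 1 count in hIDR2, a ratio of 117 (20.7 to 4656). Members outside multigene families gave medians of 1.05, 1.57, 1.63, 3.01 and 2.88, a grouping chosen after the values of the whole list were seen and before its own medians were computed.

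MERVL followed the same order. The internal part of this retrovirus, MERVL-int, took 2044.6 CPM of all repeat counts in the library labelled JMJD2C_FL, 842 in JMJD2C_Mut, 2518 in JMJD2C_Mut_hIDR1, 466 in hIDR1, 2258 in JMJD2C_Mut_hIDR2 and 408 in hIDR2. The log2 ratios of the 5 pairs were 1.28, 1.58, 1.42, 2.43 and 2.47, and MERVL-int ranked 8, 7, 9, 3 and 2 among 1153 repeat names. Its promoter repeat MT2_Mm had 0.67, 0.87, 0.76, 1.18 and 1.15. MuRRS-int (0.83, 0.98, 0.76, 1.10 and 0.71), RLTR45-int (0.61, 0.90, 0.71, 1.12 and 1.24) and IAPEz-int (0.38 to 0.62) were also higher in every pair. The young LINE-1 repeats L1Md_Gf and L1Md_A had 1.43 and 0.75 for JMJD2C_FL against JMJD2C_Mut, and 0.26 and -0.26 for JMJD2C_Mut_hIDR2 against hIDR2. L1Md_T was at -0.04 in the latter pair. Another LINE-1 repeat, L1Md_F, was higher in every pair (0.68 to 0.81). L1Md_F2, L1Md_F3, L1_Mus1, MT2C_Mm, IAPLTR1_Mm and MMERVK10C-int were also higher in every pair, with intervals above 0. MMETn-int was lower in every pair (-0.60 to -0.11), but at 0.05 for JMJD2C_Mut_hIDR1 against hIDR1 when scaled to gene counts. MT2B, B1_Mm, B2_Mm1a and B2_Mm2 were slightly lower in every pair, the lowest at -0.10, but at up to 0.22 (B1_Mm) for JMJD2C_FL against JMJD2C_Mut when scaled to gene counts. In every pair the satellite repeats GSAT_MM and SYNREP_MM had intervals that spanned 0. A read may be counted at several copies, and bootstrap intervals over copies do not describe the spread between cultures.

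**Figure D4:**
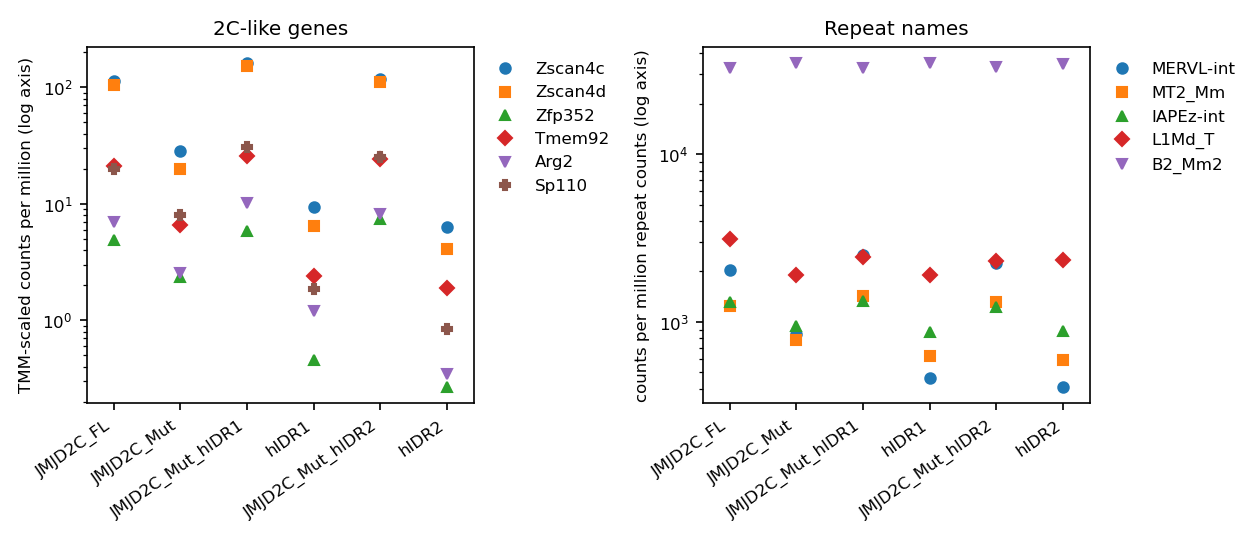
Points show TMM-scaled CPM of the 2C-like genes Zscan4c, Zscan4d, Zfp352, Tmem92, Arg2 and Sp110 (left), and CPM of all repeat counts for 5 repeat names (right), in the 6 overexpression libraries on log axes. MERVL-int lies at 2044.6, 2518 and 2258 in the libraries labelled JMJD2C_FL, JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2 and at 842 or below in the others.

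Other lists had medians outside the central 95% of matched random lists in at least 3 pairs, with values in the same order of pairs. Hypoxia and glycolysis genes had medians of 0.42, 0.78, 0.90, 0.80 and 0.96, all at percentile 99.99 or 100, and Egln3, an oxygen-sensing hydroxylase gene, had log2 ratios of 1.98, 2.49, 2.81, 2.23 and 2.51. Imprinted genes had medians of 0.79, 0.73, 0.74, 0.64 and 1.23 (percentiles 99.97 to 100), with Peg10 at 805 CPM in JMJD2C_FL and 80.5 in JMJD2C_Mut. Germline genes had 0.07, 0.24, 0.23, 0.54 and 0.59, at percentile 85.7 and so within the random range in the first pair and 99.2 or above in the others, with Asz1, a piRNA pathway gene, between 2.79 and 4.67. Primitive endoderm genes had 0.28, 0.48, 0.32, 0.64 and 1.10 (percentiles 97.75 to 100), with Gata6 between 0.82 and 2.05. Naive pluripotency genes had -0.08, -0.39, -0.34, -0.48 and -0.40, at percentile 46.2 in the first pair and 0.14 or below in the others. Their member Dppa3 was nonetheless higher in every pair (1.71 to 3.61), and Lin28a was at -1.38, -1.49 and -1.23 against JMJD2C_Mut. Cell cycle genes had -0.23, -0.32, -0.30, -0.31 and -0.50 (percentiles 4.64, 1.18, 0.81, 2.99 and 0.02, within the random range in the first pair and the fourth), with Ccne1 at -0.72, -0.61, -0.75 and -0.75 in the first 4 pairs.

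The remaining lists, histone genes apart, lay within the central 95% of random lists in most pairs, with values in the same order. Primed pluripotency genes had medians of 0.28, -0.09, 0.02, -0.37 and 0.16, and trophectoderm genes 0.22, 0.08, 0.34, 0.14 and 0.28. Mesoderm and neural genes (6 or 7 genes) had 0.14, 0.60, 0.67, 1.23 and 1.12, and fibroblast genes 0.09, 0.06, 0.41, 0.39 and 1.17. Genes of the H3K9 and DNA methylation machinery had -0.10, -0.16, -0.24, -0.17 and -0.25 with 0 of 19 past 2-fold. Targets of p53 had 0.21, 0.15, 0.02, 0.35 and -0.06, and interferon response genes 0.41, -0.15, -0.20, -0.15 and -0.02, with Cxcl10 higher in every pair (1.91 to 4.50). Mitochondrial transcripts had -0.10, 0.03, -0.12, 0.52 and -0.14, and histone genes, with 4 genes in the first pair only, 1.13. Of these medians, those above the central 95% were mesoderm and neural genes in the last 2 pairs (percentiles 99.55 and 98.6), fibroblast genes in the third and last (97.9 and 99.9), p53 targets in the first and the fourth (98.9 and 99.75), mitochondrial transcripts in the fourth (99.7) and histone genes (99.3); none were below it. 

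The genes called in TKO were placed in the same pairs. Those called up in TKO had medians of 0.15, 0.03, 0.03, -0.05 and -0.08, and those up at least 2-fold had 0.40, 0.27, 0.37, 0.31 and 0.63. Genes called down in TKO had -0.21, -0.15, -0.12, -0.14 and -0.10, and those down at least 2-fold had -0.29, -0.05, 0.01, 0.05 and 0.13. Among matched random lists the genes called up were at percentiles 100, 100, 100, 99.1 and 12.1. In the fourth pair their median of -0.05 thus lay above the random lists. Those called down were at 0, 0, 0, 0 and 18.6. The genes up at least 2-fold were at percentile 100 in all 5 pairs. The genes down at least 2-fold were at percentiles 0, 37.7, 71.1, 99.9 and 100, so their direction changed between pairs.

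Log2 ratios of JMJD2C_FL against JMJD2C_Mut correlated with those of the other pairs across 14010 genes, which are not independent replicates. Pearson's r was 0.787 with JMJD2C_Mut_hIDR1 against JMJD2C_Mut (Spearman's rho 0.728) and 0.793 with JMJD2C_Mut_hIDR2 against JMJD2C_Mut (rho 0.720). Simulated libraries that differ only by the spread between knockout replicates gave r = 0.504 and 0.506 through the shared library. Their covariances were 0.0181 and 0.0183, compared with 0.360 and 0.326 observed. That spread may hold no difference between cultures, so the simulated values may be too low for unchanged cultures. The library labelled JMJD2C_Mut cannot be split, so part of the excess may come from that library itself. The pairs without a shared library had r = 0.547 (rho 0.483) for JMJD2C_Mut_hIDR1 against hIDR1 and 0.448 (rho 0.320) for JMJD2C_Mut_hIDR2 against hIDR2, with simulated values of -0.00317 and 0.000886. Of 861 genes at least 2-fold higher in JMJD2C_FL, 547 were also higher in JMJD2C_Mut_hIDR1 against JMJD2C_Mut, where independence gives 50.7 and simulation 3. The pair with hIDR2 as control shared 444, where independence gives 92.6 and simulation 0.2. Simulated libraries differ only by replicate spread, so few of their genes can pass 2-fold. Their shared counts are low by construction and are no reference for these overlaps. The overlap of 547 is between pairs that share JMJD2C_Mut, so independence is too low a reference there. On the lower side, 159 and 91 of 465 genes were shared with the pairs that have hIDR1 and hIDR2 as controls, where independence gives 36.9 and 24.2.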

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

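The tests on shared reads of gene families and on a chromosome-wide shift were written down before their results were seen; those on exchanged labels, uncounted construct RNA, scaling and culture were chosen only after the result was seen.

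Repeats were picked out where both pairs of a mutant with an added disordered region and its control had bootstrap intervals that excluded 0, on opposite sides, named genes where both ratios were at least 2-fold in opposite directions, and list medians where both lay outside the central 95% of random lists with opposite signs. Only 3 items met this, 2 repeats and 1 gene. Other repeats and list medians also had opposite signs, but did not meet these conditions. L1Md_A, a young LINE-1 repeat, had a log2 ratio of 0.24 for JMJD2C_Mut_hIDR1 against hIDR1 and -0.26 for JMJD2C_Mut_hIDR2 against hIDR2. RLTR4_Mm, a retroviral promoter repeat, had 0.0777 and -0.37. The gene Fgf15 had -1.13 and 1.08. Each value compares 1 library with 1 library, and the difference between the pairs was not tested.

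Kdm4c reads were raised only in the library labelled JMJD2C_Mut. If labels had only been exchanged and all construct RNA were counted on Kdm4c, 4 libraries should lie well above the lowest, but only 1 library lay above 1.5 times the lowest of the 6. This speaks against an exchange only where construct RNA is counted, so exchanged labels and uncounted construct RNA cannot be told apart: JMJD2C_FL had 1.09 times the mean Kdm4c level of hIDR1 and hIDR2, and the construct sequences are not given in the sources used here. A codon-altered or human construct, a weak or lost construct, or a wrong label in 1 library stay open, and no biological explanation was tested.

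The 2C-like genes and MERVL-int were higher in the libraries labelled JMJD2C_FL, JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2 than in those labelled JMJD2C_Mut, hIDR1 and hIDR2. Scaling, which moves all genes alike, does not account for this: the 2C-like median exceeded the median of all genes by at least 1.77 in every pair, and with library sizes only it was 1.79, 2.19, 1.92, 3.89 and 4.39. Shared reads of gene families are not the whole cause, since list members outside such families had a median of at least 1.05 in every pair. Their medians were lower than those of the whole list in each pair, and how much shared reads add was not tested. By the labels these are the JMJD2C constructs with a complete or substitute disordered region, but that the region drives the rise is a hypothesis that was not tested, and Kdm4c reads in the 3 libraries were at 1.01, 0.994 and 1.04 times the median of the 6. With 1 library per construct, culture or clone and construct cannot be told apart.

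X-linked genes were higher in the same libraries. Scaling, which moves all chromosomes alike, is excluded as the cause, because the X-linked median exceeded the highest autosomal median by 0.59 in JMJD2C_FL against JMJD2C_Mut. Shared reads of the Magea, Xlr and similar families are excluded as the whole cause, because the median without them was at least 0.35 in every pair. A chromosome-wide shift fits in JMJD2C_FL against JMJD2C_Mut, the pair named for the test beforehand. There 100% of windows of 20 X-linked genes lay above the autosomal median. The test counts only the direction of windows. Relative to the autosomal median they lay between 0.34 and 2.37, so the shift was not of uniform size. The share of windows above the autosomal median was 100% in the other pairs with JMJD2C_Mut and 96.3% against hIDR1. Against hIDR2 it was 85.2% (23 of 27, lowest window -0.35), under the 90% set beforehand, so the last pair stays undecided. Y-linked genes, named below, were also higher in the same libraries, so the rise was not confined to the X chromosome. Another X copy number or X activity, which may have no link to the constructs, was not measured.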

How the results depend on the processing

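All 4 knockout libraries exceed 51.9 M counts, so depth limits mainly genes near 1 CPM, and with 2 libraries per group the spread is estimated from few samples. The overexpression pairs have no replicates, so their counts depend on the threshold and the filter by construction. Several alternatives were added only after the data were seen: the pairs and correlations without X and Y genes, the 2C-like members outside multigene families, and knockout calls with a fold threshold. Values for the 5 pairs are given in the order JMJD2C_FL against JMJD2C_Mut, JMJD2C_Mut_hIDR1 against JMJD2C_Mut, JMJD2C_Mut_hIDR2 against JMJD2C_Mut, JMJD2C_Mut_hIDR1 against hIDR1 and JMJD2C_Mut_hIDR2 against hIDR2.

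The 10012 TKO calls became 8484 with DESeq2, 10001 with RLE, 9981 with library sizes only, 10069 with no filter, 8881 at a mean CPM of at least 1 and 10259 with the replicate block. Leaving out 1 library, which assumes that the lone library varies like the other group, gave 8359 to 9378. RPKM with limma gave 7762, 7666 and 7378 with pseudocounts of 0.1 and 1 and with a mean RPKM of at least 1. Every gene called in common kept its direction. Genes called down numbered 3137, 3093 and 3317 in the RPKM fits, against 5187, which scale by library size; the cause was not tested further. Genes called at 2-fold or more numbered 2415 in the TMM fit, 1257 at a mean CPM of at least 1, 805 at a mean RPKM of at least 1, where fewer genes are tested, and 495 with log2(RPKM + 1), which shrinks small values. Of 1098 values for 89 named genes, 1063 stayed the same, 32 lost the call, 3 gained it and 0 reversed. With an estimated correlation 0 of the 7 called lists stayed called. The 2C-like list was also lost with library sizes only, naive pluripotency with library sizes only, the replicate block and without either TKO library, germline without TKO replicate 2 and mitochondrial transcripts without Ctrl replicate 2. Fibroblast and cell cycle genes were gained with the block and without either TKO library.

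For the 5 pairs, a mean CPM of at least 5 gave 377, 352, 342, 532 and 629 genes at least 2-fold higher and 207, 298, 89, 757 and 492 lower, since fewer genes are counted. No filter gave 2921, 3052, 3030, 3789 and 4236 higher and 1638, 1759, 1060, 2141 and 1888 lower. A 1.5-fold threshold gave 1891, 2013, 1851, 2370 and 2514 higher and 1705, 2149, 1171, 2985 and 2327 lower. A pseudocount of 0.1 on RPKM, which has no TMM scaling, gave 302 lower in the first pair and 133 in the third. Library sizes only gave 371 and 159. The medians over all genes were 0.022 and 0.033 with library sizes only and 0.021 and 0.032 with RPKM, against -0.043 and -0.041 with TMM. Part of the drop thus goes with the scaling, and the rest was not tested. Without X and Y genes 651, 681, 683, 1022 and 1311 were higher and 455, 553, 220, 1084 and 725 lower. Lower genes outnumbered higher ones in the fourth pair under this setting, at a mean CPM of at least 5 and at 1.5-fold, and in the second pair at 1.5-fold.

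The 2C-like medians outside multigene families were 1.05, 1.57, 1.63, 3.01 and 2.88. In the last pair the median was 4.07 with a prior count of 5, which shrinks low counts, and 4.10 with RPKM. MERVL-int relative to gene counts had log2 ratios of 1.50, 1.77, 1.55 and 2.60 in the first 4 pairs, and without its 5 most covered copies 1.38, 1.70, 1.53, 2.64 and 2.67; the cause was not tested. MMETn-int in JMJD2C_Mut_hIDR1 against hIDR1 went from -0.11 to 0.05 relative to gene counts. The correlations of JMJD2C_FL against JMJD2C_Mut with the other pairs were 0.748, 0.752, 0.499 and 0.384 without X and Y genes. They were 0.799 for JMJD2C_Mut_hIDR2 against JMJD2C_Mut with a prior count of 0.5 and 0.560 for JMJD2C_Mut_hIDR1 against hIDR1 at a mean CPM of at least 5; the cause was not tested. Of 2335 values for named genes and repeats in the pairs, 461 moved. For genes this means past the counting interval, and for repeats by more than the bootstrap SD. None of the values at 2-fold or more changed sign. Among smaller ones 38 did, 26 of them repeats relative to gene counts, with log2 ratios of at most 0.26 in size.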

Other observations

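The 4 gene lists tested here were assembled after the named genes of the report had been seen. Each prediction was written before its list was measured as a list, but members such as Ccnd1, Sesn2, Kdm3a and P4ha2 were in fixed lists. Ier3 is in both the HIF and ERK lists and Ddit4 in both the HIF and ATF4 lists, so the lists overlap. Adjusted p are over these 4 lists. Genes of the HIF pathway outside the fixed hypoxia and glycolysis list fell in TKO, with 19 of 23 called down and 3 up (median -0.87), among them Ankrd37 (-2.28), Slc16a3 (-1.67), Ak4 (-1.59) and Egln1 (-1.58). The 3 that rose were Pfkfb4 (0.83), Kdm3a (0.28) and Jmjd6 (0.11). In the overexpression pairs the same list had medians of 0.40, 0.65, 0.78, 0.61 and 0.60, so it was higher in the libraries labelled JMJD2C_FL, JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2.

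Targets of ERK signalling rose in TKO, with 17 of 19 called up and 1 down (median 0.84), led by Etv1 (3.59), Myc (3.45) and Phlda1 (3.21), with Egr1 (1.74) and Dusp6 (1.56) among the others and Ier3 at -1.11. Targets of YAP and TEAD had 14 of 18 up and 2 down (median 0.85), with Lats2 (2.18), Ccn2 (1.81) and Ccn1 (1.64) up. Fibroblast genes moved with them, with 7 of 8 up and a median of 1.19, among them Tagln (2.75) and Col1a2 (2.40). Targets of ATF4 had 6 of 26 up and 16 down in TKO (median -0.23, camera adjusted p = 0.0346, or 0.237 with an estimated correlation). Atf3 (2.53) was up and Asns (-0.74) down. Slc7a11 (2.83, SE 0.63) was up at a very low level, from 0.078 to 0.55 CPM.

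IAPEy-int, a repeat chosen after its values were seen, had log2 ratios of 2.30, 2.83, 2.72, 3.26 and 3.33 in the 5 pairs, above those of MERVL-int. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d and the X-linked RNA Xist also differed between the overexpression libraries. These genes too were chosen after their values were seen. Xist had 26.6, 18.8 and 18.4 CPM in the libraries labelled JMJD2C_FL, JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2 and 1.68, 2.52 and 2.82 CPM in those labelled JMJD2C_Mut, hIDR1 and hIDR2. Ddx3y had 60.5, 39.1 and 37.4 CPM and 18.1, 14.8 and 6.10 CPM in the same libraries. In TKO the X-linked median was 0.03.

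The fall of hypoxia and glycolysis genes in TKO was tested for reach beyond the list. The added HIF list fell with a camera adjusted p of 1.12e-22, and 0.0176 with an estimated correlation. These were adjusted over the added lists only, which were assembled after named genes had been seen. With an estimated correlation the unadjusted camera p of the HIF list was 0.00817. The fixed hypoxia and glycolysis list had 0.00585, and an adjusted p of 0.0936 over the 16 fixed lists. The lower adjusted p of the HIF list thus goes with adjusting over fewer lists. HIF genes outside the fixed list also fell, but HIF pathway output was not tested independently. Oxygen and cell density are not given in the sources used here, so a culture difference could give the same fall.

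The genes highest in TKO led to a test of ERK and YAP targets. The ERK list rose with a camera adjusted p of 4.65e-22 (0.0176 with an estimated correlation) and the YAP list with 3.53e-11 (0.0630). These too were adjusted over the added lists only. With an estimated correlation the unadjusted camera p of the ERK list was 0.00882. That of the fixed hypoxia and glycolysis list was 0.00585, and its call was lost among the 16 fixed lists. The ERK call with an estimated correlation thus rests on the number of lists adjusted together. ERK targets rose in TKO, but ERK pathway output was not tested independently. For the YAP list, a larger share of fibroblast-like cells could give the same rise, since 7 of 8 fibroblast genes rose too. The labels list a MEK inhibitor in the medium of all cells and do not say whether the medium differed between the groups. A difference in inhibitor exposure could therefore give this pattern without the knockout, and no value here decides between them.

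Chac1 and Nupr1 were lower in the libraries labelled JMJD2C_Mut_hIDR1 and JMJD2C_Mut_hIDR2, which led to a test of other ATF4 targets. Their median log2 ratios were -1.12 against hIDR1 and -0.72 against hIDR2, with 24 and 23 of 26 genes lower, and the higher percentile of the 2 among matched random lists was 0. Against JMJD2C_Mut the medians were -0.62 and -0.55, also at percentile 0, so the list was low relative to JMJD2C_Mut as well as to the regions alone. This is consistent with a weaker amino acid stress response in those libraries, and 1 library each cannot separate construct from culture.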
